A study of Mus musculus with 2 samples.

How the data were processed

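RNA was sequenced from cells isolated as fibroblasts from the lungs of bleomycin-treated Foxf1fl/fl mice and of myoFoxf1 KO mice, with 1 library per genotype, and libraries were made with the Nextera XT kit, per the labels' protocols. This kit does not mark strand, so reads of overlapping or antisense genes cannot be told apart. The protocols state tamoxifen at 40 mg/kg on days 2 to 4, but not how many animals went into each library or how the cells were isolated.

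The authors deposited 1 table of 38972 gene rows that holds, for each library, estimated counts of reads per gene and FPKM. The submitters' processing notes name TopHat and Cufflinks and the builds GRCm38 and mm10, without roles or versions. The deposited estimated counts were not whole for 76.1% of genes with reads in the control and 73.3% in the knockout, and were rounded to whole numbers here. The deposited FPKM equalled the estimated count divided by a gene length common to both libraries and by the total of the library, so FPKM gave no independent measurement and was used only in alternatives. All value columns were assigned to a library by their names. The table held no rows for mitochondrial genes, so the list of mitochondrial transcripts has no values. Of the gene identifiers 37570 were found in the GENCODE annotation of GRCm38 supplied as reference, and 26414 had the same chromosome, start and end there.

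The rounded counts summed to 16145959 in the control and 15122824 in the knockout. Libraries were scaled with TMM in edgeR 4.0.16 under R 4.3.3, and CPM were computed on the scaled library sizes. The log2 ratio of knockout over control used a prior count of 0.5 scaled to each library. Its interval is the exact conditional binomial (Clopper-Pearson) 95% interval, computed with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15. Reads without molecular identifiers are not independent molecules, so these intervals and limits cover counting error only. The bootstrap intervals and resampled limits under other observations come from 10000 draws of genes within lists. They cover the choice of genes only, and say nothing on the spread between animals. Where a library had 0 reads, the ratio was bounded with 3 reads in that library. Genes with at least 1 CPM in either library and at least 20 reads in the sum of both were measured, 14455 in all. A gene was called when its ratio was at least 2-fold in either direction and the interval excluded 1. Comparisons between these 2 libraries carry no information on the spread between animals.

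Before the data were examined, 41 gene lists were fixed for matrix, adhesion, signalling, inflammation, proliferation, metabolism, stress, library quality and cell types. Of their 780 symbols, 15 had no row in the table. Each list with at least 5 measured members was summarised by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart at a percentile of at most 2.5 or at least 97.5. Another 11 lists were written after the data were seen, and their values are given as such. Named genes were chosen by a rule written beforehand: Foxf1, Cdh2 and Cdh11; the 12 highest and 12 lowest ratios among called genes of at least 10 CPM in the higher library whose symbol is not that of a predicted gene; up to 4 called members of each list by size of the ratio, or the 2 most expressed where none was called; and the most abundant member of each cell type list. Acta2, Col1a1, Col3a1, Sftpc, Fap, Tpm2, Prox1, Has2, Tnfaip6, Xist and the members of the added lists were named outside this rule, after their values were seen. A few genes that the rule takes are not reported here.

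The alternatives were scaling by total reads alone, median-of-ratios size factors of DESeq2 1.42.0, log2 of the deposited FPKM plus 1 or plus 0.1 with at least 1 FPKM in either library, other count filters, 1.5-fold and 4-fold rules, an interval that excludes the 2-fold threshold itself, random lists without matching, and a prior count of 2. Added after seeing the data were ratios relative to the fibroblast markers and a correction for GC content and length, which subtracted lowess trends (span 0.3, statsmodels 0.14.6) on the GC content and log2 length of the longest transcript of each gene. A GC content was found for 98.9% of measured genes.

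The calculations were tested on simulated data, and the list percentiles on the real ratios. Poisson counts were drawn for the real genes from their mean CPM and the real library sizes, with 200 genes changed by known folds. Of the measured changed genes, 2.04% were called at a true fold of 1.5, 46.9% at 2, 98.0% at 3 and 100% at 4, and 0.306% of 14073 unchanged genes were called. The intervals held the true ratio for 95.4% of genes. The simulated counts were Poisson, as the interval assumes, and held no spread between animals. The shares called and the coverage therefore check the calculation and are not error rates for the real libraries. On the real ratios of the measured genes, 8.0% of 100 random lists of 20 genes stood apart. Of 30 such lists shifted by 0.5 in log2, 70.0% stood apart higher. A trend on GC content added to simulated ratios was removed to within a median of 0.005 in log2.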

Results

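The series profiled RNA from cells isolated from mouse lungs as fibroblasts, the cells that lay down the collagen of the lung. One library came from Foxf1fl/fl control mice and 1 from myoFoxf1 KO mice, in which a tamoxifen-activated Cre driven by the smooth muscle actin promoter deletes Foxf1, the gene of a forkhead transcription factor of the lung mesenchyme. Bleomycin, a drug that scars the lung, was given at 1 or 2 U/kg for 2 to 4 weeks in the protocol of the series, and the labels do not say which dose or duration these cells had. The title of the knockout sample does not name bleomycin, unlike that of the control, and the design text names it once for both, so treatment of the knockout mice is not certain from the labels. The control library held 16145959 reads assigned to genes and the knockout library 15122824. Across the 14455 genes measured in both together, the log2 CPM (read counts scaled to library size) of the libraries correlated with a Pearson coefficient of 0.940, a value across genes, which are not independent replicates. With 1 library per group the differences have no replicate check and no p-value is given. A gene was called higher or lower when its CPM differed at least 2-fold and the exact 95% interval of the ratio excluded 1, and this interval covers counting error only.

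The first question was the level of Foxf1 itself and of the cadherins Cdh2 and Cdh11, the adhesion genes named in the title of the series. Foxf1, on chromosome 8 from 121084386 to 121088144 in GRCm38, was lower in the knockout library, with 158 reads (8.77 CPM) in the control and 49 reads (3.61 CPM) in the knockout, a log2 ratio of -1.27 (95% interval -1.77 to -0.81). The labels do not say which part of Foxf1 is deleted, so reads from the part left in place would still be counted. Fendrr, the noncoding gene that lies beside Foxf1 on the same chromosome, was lower by a log2 ratio of -2.37 (-3.61 to -1.41), from 64 to 9 reads. Cdh2, the gene of N-cadherin on chromosome 18 from 16588877 to 16809246, was higher with a log2 ratio of 1.03 (0.03 to 2.14), which rested on 14 reads in the control and 22 in the knockout. Cdh11, on chromosome 8 from 102632995 to 102785111, was not called, with 325 and 179 reads and a log2 ratio of -0.45 (-0.72 to -0.18). After removal of the trend of the ratios on GC content and transcript length, Foxf1 was at -0.86 and Cdh2 at 0.91, and neither was called, and Cdh11 was at -0.93, also without a call. Cdh2 was also not called when libraries were scaled by total reads alone, at 0.73. Scaling to the median of the fibroblast markers raises every ratio by the same amount. Relative to it Foxf1 was not called, at -0.33, and Cdh11 turned to 0.50. Cdh2, already called higher, kept its call by construction.

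**Figure D1:**
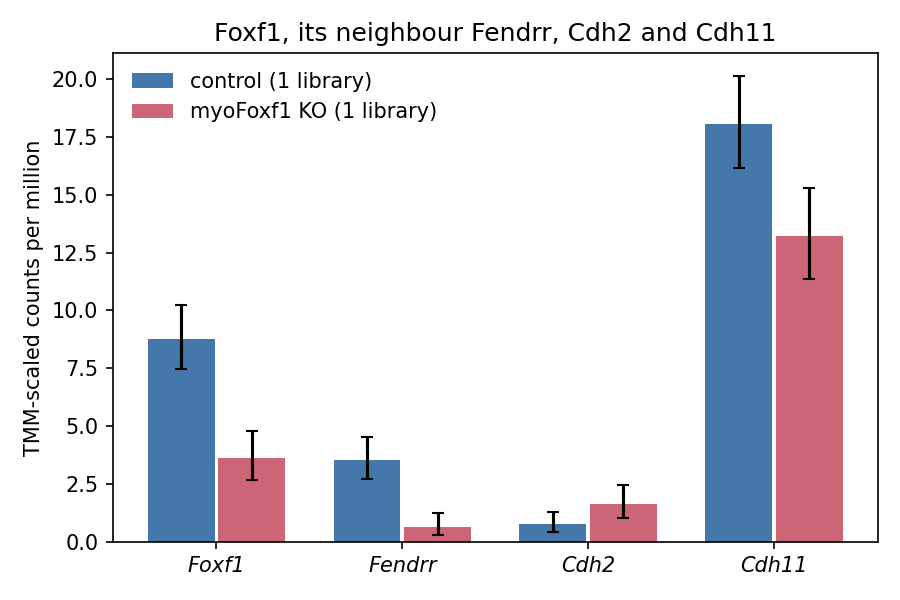
TMM-scaled CPM of Foxf1, Fendrr, Cdh2 and Cdh11 in the control and the myoFoxf1 KO library, 1 library each; error bars are exact Poisson 95% intervals and cover counting error only. Foxf1 stood at 8.77 and 3.61 CPM, Fendrr at 3.55 and 0.664, Cdh2 at 0.777 and 1.62, and Cdh11 at 18.0 and 13.2.

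The 2 libraries held transcripts of several lung cell types besides fibroblasts. Lyz2, the lysozyme gene of macrophages, was the most abundant gene in both, at 11221 CPM in the control and 24231 CPM in the knockout, a log2 ratio of 1.11. The macrophage markers had a median log2 ratio of 0.85, at percentile 99.9 of random lists of the same size and expression, and 9 of 24 were called higher and none lower. Itgam (1.51), Mrc1 (1.46), Ctss (1.28) and Ptprc (1.27) led them. With the GC and length correction the list median was 0.975 (percentile 100), and 12 of 24 were called higher and none lower. Mrc1 at 0.91 and Ptprc at 0.51 were then short of a call. So were Lyz2 at 0.80, Ctss at 0.97 and Ptprc at 0.95 with total reads alone. Neutrophil markers had a median of 0.87 (percentile 99.9), with 4 of 10 called higher, S100a8 at 2.27, Ngp at 2.08 and S100a9 at 1.99 among them, and Ltf lower at -1.44.

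Epithelial markers were lower in the knockout library, with a median log2 ratio of -1.38 (percentile 0) and 19 of 25 called lower, or -0.93 and 11 of 25 with the correction. Scgb1a1, the club cell secretoglobin, stood at 7161 CPM in the control and 1887 CPM in the knockout, and Sftpc, the surfactant gene of type II cells, at 5413 and 2071 CPM. Krt5 (-4.37, on 66 reads in the control and 2 in the knockout), Foxj1 (-2.58), Cldn3 (-2.55) and Krt7 (-2.41) had the lowest ratios of the list. All 9 measured mesothelial markers were called lower, with a median of -1.67, and Upk3b, a marker of the lining of the pleura, fell from 104 to 16.6 CPM. With the correction 8 of the 9 were called, and Krt19, the most abundant of them at -1.52, was at -0.80. Endothelial markers had a median of -0.97 (percentile 0) with 8 of 20 lower, Plvap (-2.21) and Egfl7 (-1.93) among them, and Prox1 higher (1.04, corrected 0.53 and not called), while Cav1, the most abundant, had a ratio of 0.93 and was not called. Among erythroid genes the median was -1.31 and 4 of 5 were lower, Hba-a1 (-1.72) and Hbb-bs (-1.31) included. The globin copies share reads, and none of the 5 was called after the correction.

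Lymphocyte markers went both ways. The B-cell genes Cd79a (-2.10) and Cd79b (-1.68) were lower and the T-cell gene Cd8a (2.18) was higher, and the list median of -0.10 (percentile 42.9) did not stand apart. It stood apart lower with the correction, at -0.42, and among genes of at least 10 CPM, at -0.61. Pericyte markers had a median of -0.05 (percentile 69.1), or -0.48 with 1 higher and 1 lower once corrected. Gja4 (-1.97, on 38 and 7 reads) and Pdgfrb (-1.14) were lower and Cspg4 (1.15) and Rgs5 (1.07, on 18 and 29 reads) higher. Pdgfrb at -0.87 and Rgs5 at 0.48 lost their calls with the correction, as Cspg4 at 0.84 did with total reads alone. Smooth muscle markers had a median of -0.38 (percentile 47.4), or -0.26 with 2 lower once corrected, and Cnn1 (-1.40) alone of the 7 was called, while Des, the most abundant, was at 0.34. Neural crest and glial markers had a median of 0.53 (percentile 93.9), with S100b (1.83) among the genes called higher. This list stood apart at 1.22 once corrected, while its median turned to -0.69 with log2 of FPKM plus 1 and -0.76 with FPKM plus 0.1.

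**Figure D2:**
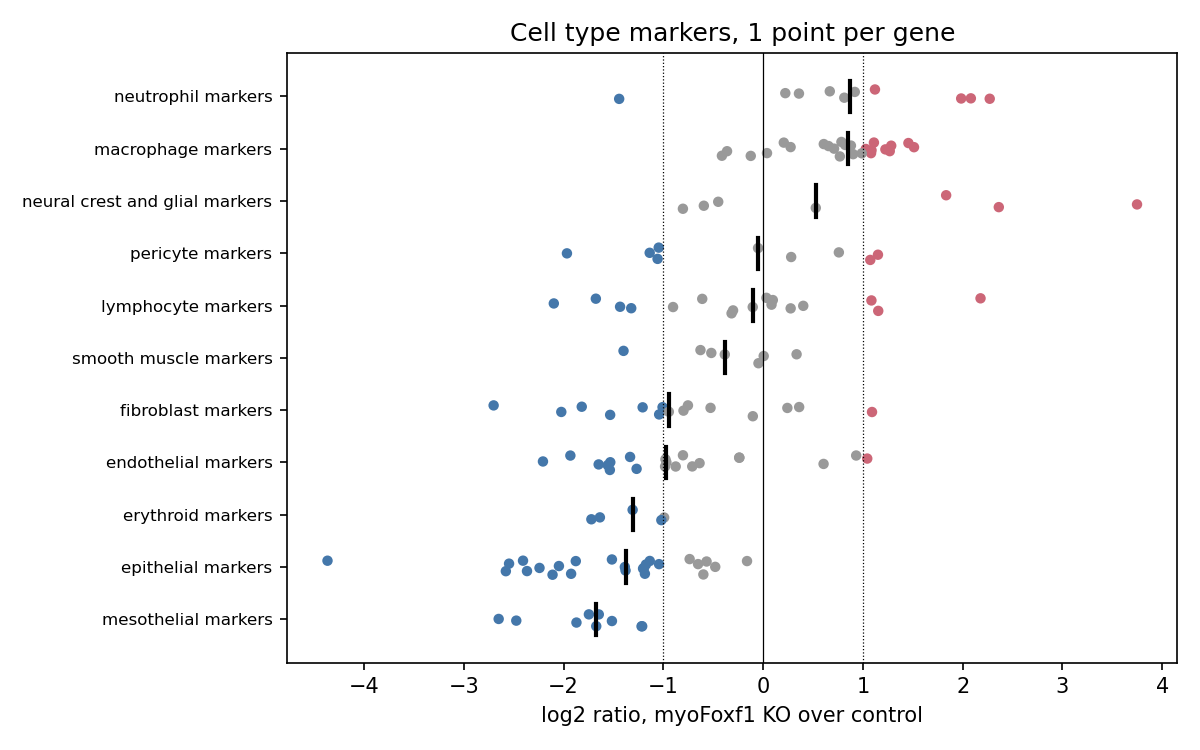
Log2 ratio of the myoFoxf1 KO over the control library for each measured marker gene, 1 row per cell type list; black bars are list medians, dotted lines mark 2-fold, and red and blue points are genes called higher and lower. Macrophage and neutrophil medians lay at 0.85 and 0.87 and mesothelial and epithelial medians at -1.67 and -1.38.

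Fibroblast markers were lower in the knockout library as a group, with a median of -0.94 (percentile 0). Of 15 measured markers 7 were called lower, among them Inmt (-2.70), Gpx3 (-2.02), Mfap4 (-1.82) and Pi16 (-1.53), and Fap, the fibroblast activation protein, was called higher on 29 and 47 reads but not after the GC and length correction, at 0.51. Vim, which macrophages also express, was the most abundant at 2870 and 3687 CPM and had a ratio of 0.36. The list median after the correction was -0.93, with 6 of the 15 lower and none higher. Lung mesenchyme transcription factors had a median of -0.91 (percentile 0.5) and 8 of 18 were lower. Tbx4 (-2.76), Tbx2 (-2.09), Tcf21 (-1.79) and Hoxa5 (-1.56) had the lowest ratios, all of them below that of Foxf1.

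Genes of fibrillar collagens and collagen fibre assembly had a median of -0.65 (percentile 0.01), with 11 of 26 called lower and none higher. Among them were the lysyl oxidase Loxl1 (-2.16), the prolyl hydroxylase subunit P4ha2 (-2.16), the collagen chaperone Serpinh1 (-2.05) and the procollagen enhancer Pcolce (-1.96). Col1a1 stood at 212 and 106 CPM, a ratio of -1.01 that was -0.44 and no longer called with the correction, and Col3a1, at -0.56, was not called. In the list 6 of the 26 were then lower and the median was -0.76. Col1a1, Col1a2, Dcn and Lum are also fibroblast markers, so these lists are not independent. The fibroblast, epithelial, endothelial and mesothelial medians were lower in the same library, and the macrophage median was higher.

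Non-collagen matrix genes had a median of -0.67 (percentile 0), with 10 of 27 lower and 3 higher, or -0.38 with 8 lower and 3 higher once corrected. Fbln1 (-2.14) and the elastic fibre gene Mfap4 (-1.82) were lower. Spp1, the gene of osteopontin, rose from 1006 to 5137 CPM (2.35, 95% interval 2.33 to 2.38), and Fn1, the gene of fibronectin, rose from 543 to 1809 CPM (1.74). Macrophages can express both. Basement membrane genes had a median of -0.78 (percentile 0.04), or -0.43 once corrected, with 6 of 22 lower, Col4a6 (-1.87), Lama5 (-1.79), Lamb2 (-1.59) and Col18a1 (-1.24) among them, and Col18a1 was at -0.50 with the correction. Myofibroblast contractile genes had a median of -0.63 (percentile 0.34), with 6 of 19 lower and Tpm2 higher. Cnn2 (-1.56), Cnn1 (-1.40), Smtn (-1.38) and Srf (-1.33) were lower, and with the correction Smtn stood at -0.55, Srf at -0.11, and 3 of the 19 were lower. Acta2, the gene whose promoter drives the Cre, had 565 and 225 reads, a ratio of -0.92 that was not called.

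Among 8 measured classical and type II cadherins 4 were lower and Cdh2 was higher, with a list median of -0.95 (percentile 3.85). The epithelial cadherin Cdh1 fell from 320 to 142 CPM (-1.17). Cdh13 (-1.69), Cdh4 (-1.68, on 31 and 7 reads) and Cdh3 (-1.58, on 29 and 7 reads) were also lower. This list stood apart at -1.05 when corrected. Catenins and cadherin-bound proteins (median -0.13, percentile 13.1) held 1 call in 10, Jup at -1.07, which was -0.35 after correction. Integrins did not stand apart (median -0.05, percentile 32.8). They held 4 higher and 3 lower of 18. Itgb4 (-1.97), Itga10 (-1.77, on 33 and 7 reads) and Itga3 (-1.41) were lower and Itga2 (1.43, on 9 and 19 reads) was higher. Corrected ratios of Itga3 (-0.86) and Itga2 (0.82) were short of a call, with 1 integrin then higher and 4 lower.

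Matrix metalloproteinases and their inhibitors had a median of -0.31 (percentile 3.38), with 5 of 27 higher and 4 lower, and with the correction a median of 0.042 (percentile 37.3), with 5 higher and 2 lower. Mmp12, the macrophage elastase, rose from 183 to 1221 CPM (2.73), and Mmp13 (2.59) and Adam12 (2.83, on 4 and 24 reads) were higher, while Mmp23 (-2.38) was lower. Of the mesenchymal transition factors Zeb2 (1.94) was higher, and Twist1 (-2.34, on 36 and 5 reads), Snai1 (-1.92) and Foxc2 (-1.28) were lower. Their median of -0.53 (percentile 12.5) became -0.81 and stood apart with the correction, under which Foxc2 was at -0.26. Hyaluronan genes (median 0.15, percentile 76.2) held Has1 lower (-2.13) and 9930013L23Rik (1.76), Hmmr (1.42) and Cd44 (1.16) higher. Once corrected, 9930013L23Rik was at 1.73 and still called, Hmmr at 0.87 and Cd44 at 0.65 were not, and Has1, Has2 (-1.02) and Tnfaip6 (-1.04) were called lower, with a list median of 0.013. With total reads alone the hyaluronan median was -0.16.

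Among growth factor pathways the Wnt list had a median of -1.04 (percentile 0.02), with 13 of 26 called lower, Rspo1 (-2.47), Wnt11 (-2.23), Wnt4 (-2.17) and Wnt7b (-2.02) among them, and after correction 9 were lower and the median was -0.68. BMP genes had a median of -0.68 (percentile 1.72), with 7 of 19 lower and 1 higher. Bmp7 (-2.53, on 41 and 5 reads), Id3 (-2.12), Bmp4 (-1.99) and Smad6 (-1.94) were among the lower. The Wnt, BMP and lung mesenchyme lists did not stand apart among genes of at least 10 CPM, with medians of -0.41, -0.50 and -0.74. The BMP list also did not with FPKM plus 1 (percentile 8.42) or plus 0.1 (percentile 3.71). With the GC and length correction the BMP median was -0.93 (percentile 0.01), with 9 of 19 lower and none higher. Hedgehog genes had a median of -0.88 (percentile 4.27) and 6 of 12 lower. Ihh (-2.93, on 24 and 2 reads), Gas1 (-1.94), Smo (-1.55) and Gli1 (-1.48) were among them. Smo (-0.95) and Gli1 (-0.78) lost the call with the correction, which left 3 of the 12 lower. The hedgehog list stood apart with FPKM plus 1 (-0.94) and plus 0.1 (-1.62). In the TGF-beta list (median -0.20, percentile 1.35) the activin subunit gene Inhba rose from 39.1 to 363 CPM (3.21) and Tgfbr1 was higher (1.52, corrected 0.82), while Ltbp4 (-2.19) and Ctgf (-1.56) were lower. This list did not stand apart with FPKM plus 1 (percentile 5.02) or against random lists without matching (percentile 18.4). The PDGF, FGF and VEGF list (median -0.47, percentile 2.94) held Hgf (2.25) and Igf1 (1.76, corrected 0.90) higher and Fgfr4 (-3.36) and Fgfr3 (-1.62) lower, and stood apart at -0.65 with the correction. Of 10 measured genes next to Foxf1 on chromosome 8, Fendrr and Foxc2 were lower, and the list median of -0.43 (percentile 5.18), or -0.066 once corrected, did not stand apart.

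Interferon-stimulated genes were the group with the most calls in the higher direction, 15 of 25, and none of them was lower. Their median was 1.17 (percentile 100), and 1.36 with 15 higher after the correction. Rsad2 rose from 24.6 to 231 CPM (3.23), and Ifit2 (2.95), Mx1 (2.79) and Ifit1 (2.52) followed. Inflammatory cytokines held 8 of 28 higher, such as Ccl12 (2.12), Ccl8 (1.96), Il1a (1.91) and Cxcl3 (1.86), with a median of 0.24 at percentile 63.1 that was -0.08 with total reads alone and 0.041 once corrected. Complement and antigen presentation genes had a median of -0.46 (percentile 0), or -0.16 with 1 gene higher and 1 lower once corrected, with H2-Ab1 (-1.31) and C2 (-1.25) lower, at -0.60 and -0.98 after correction, and did not stand apart against random lists without matching (percentile 3.51). Cell cycle genes had a median of 0.51 (percentile 100) with 9 of 32 higher, Cenpe (1.67), Cenpf (1.47) and Mki67 (1.46) among them. Top2a, a topoisomerase of dividing cells, went from 23.8 to 67.4 CPM. After the correction 3 were called, and Top2a (0.96) and Cenpf (0.84) were not.

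Immediate early and heat shock genes had a median of -1.15 (percentile 0), with 12 of 22 lower. Hspb1 fell from 141 to 13.2 CPM (-3.41), and Jund (-1.84), Klf2 (-1.76) and Nr4a1 (-1.53) were lower. After the correction the median was -0.44 and 2 of the 22 were called, with Hspb1 at -2.32, Jund at -0.35, Klf2 at -0.72 and Nr4a1 at -0.93. Cytosolic ribosomal protein genes had a median of -0.40 (percentile 0), or -0.17 once corrected, with none of 36 called, Rplp0 at -0.60 and Rpl4 at -0.20. Unfolded protein response genes (median -0.12, percentile 0.75) held Chac1 (-1.51) and Trib3 (-1.11) lower, and neither the list nor these 2 genes, at -0.81 and -0.35, kept the call with the correction. Senescence and p53 targets (median -0.02, percentile 17.7) held Bbc3 (-1.88, corrected -0.54), Igfbp3 (-1.77) and Igfbp5 (-1.33) lower and Plk2 (1.62) higher, and stood apart higher at 0.44 when corrected.

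Metabolic lists did not stand apart. Glycolysis and hypoxia genes were at percentile 28.8, with Hk2 (1.48) higher and Adm (-1.48), Egln3 (-1.27) and Ankrd37 (-1.18, corrected -0.94) lower. No gene of cholesterol synthesis was called among 20 (percentile 80.8), and Srebf2, an abundant member, was at -0.43. Lipid storage genes had a median of -0.14 (percentile 5.27), which the correction turned to 0.43 (percentile 92.4). They held Cd36 (1.42), Lpl (1.26) and Fabp5 (1.18) higher and Lipe (-1.34) lower, of which only Fabp5 kept the call with the correction, and it was at 0.86 with total reads alone.

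**Figure D3:**
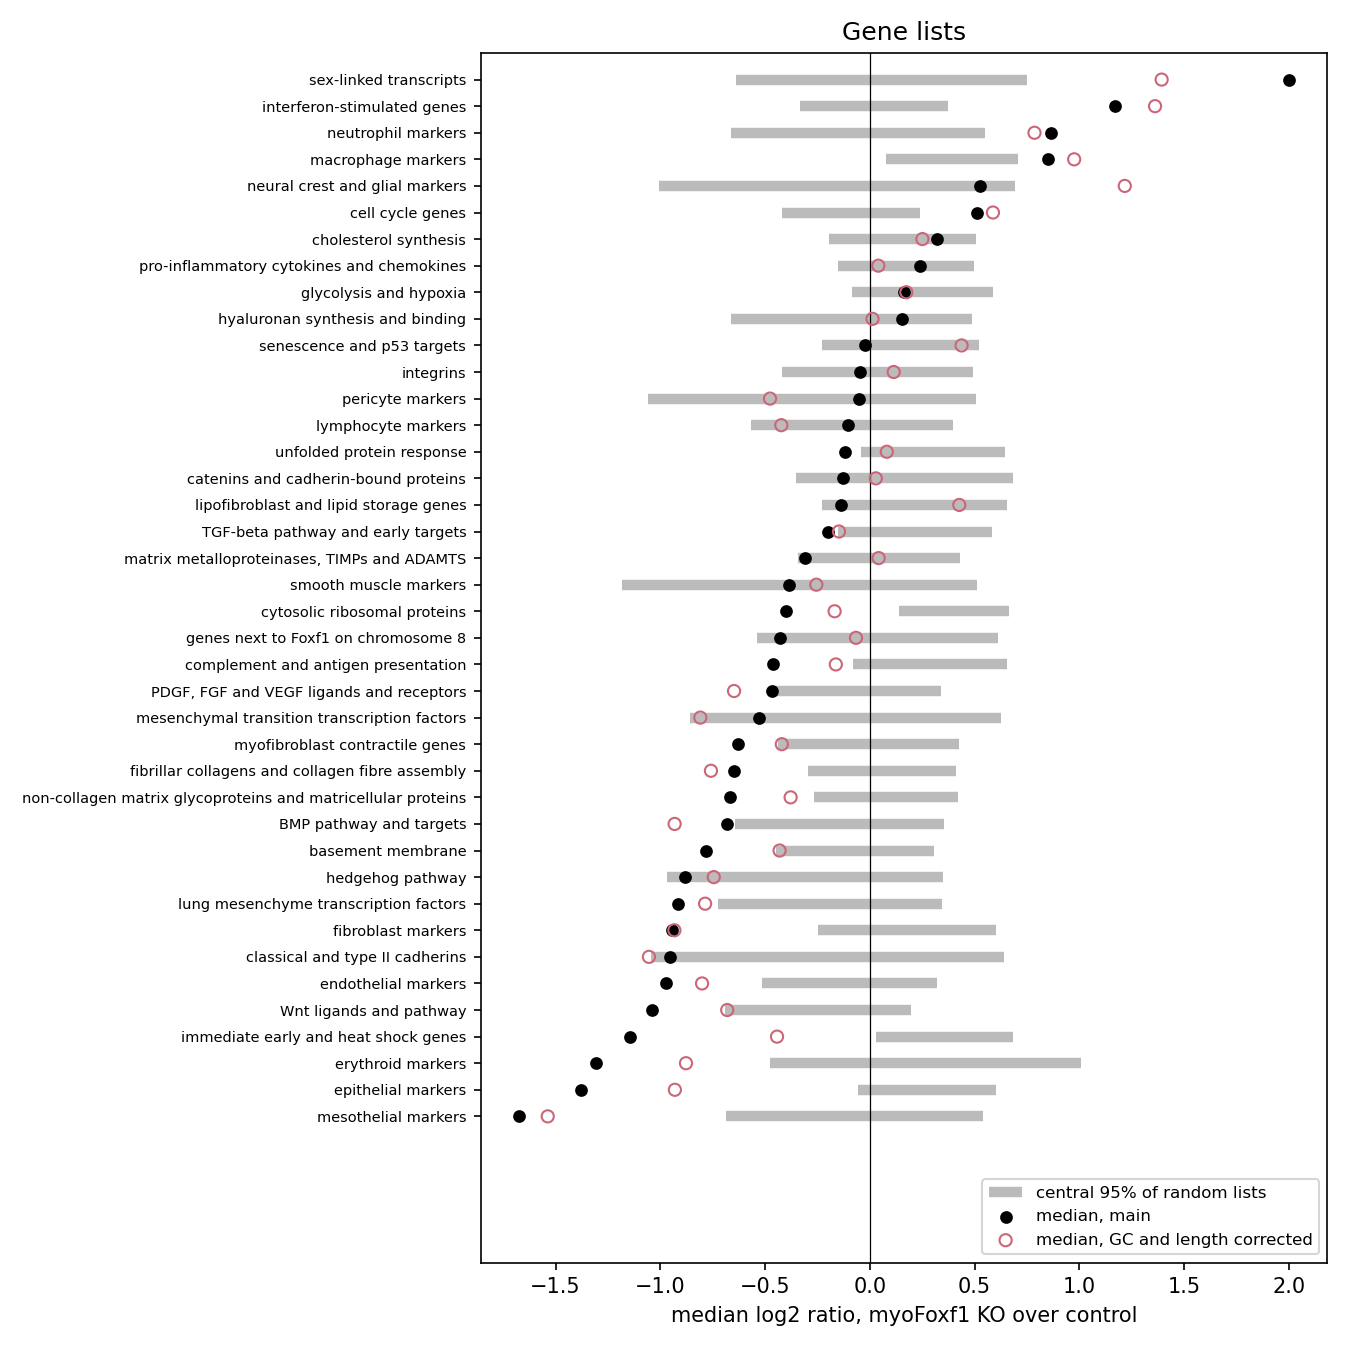
Median log2 ratio of the myoFoxf1 KO over the control library for 40 gene lists, as black points without correction and red circles with the GC and length correction. Grey bars are the central 95% of medians of random lists matched on expression and belong to the black points; interferon-stimulated genes lay at 1.17 and fibroblast markers at -0.94.

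Of the 40 lists, 5 stood apart higher and 17 lower. The percentile limits would nominally give 2 by chance, and 8.0% of 100 lists of random genes stood apart on the ratios of these libraries. Some of the lists share members, which lists of random genes do not imitate. Across all genes 1355 (9.37% of those measured) were called higher and 2053 (14.2%) lower, so that 39.8% of calls were higher. Scaling by total reads alone lowered each log2 ratio by about 0.315 and made the split 587 higher and 3212 lower, with 15.5% higher. A minimum of 10 CPM made it 907 higher and 911 lower, with 49.9% higher. The log2 ratio fell with the GC content of the transcript, with a Spearman coefficient of -0.54 across 14289 genes, which are not independent replicates. Its median was 0.70 in the 10% of genes with the lowest GC content and -0.79 in the 10% with the highest. After the correction for GC content and length, chosen after seeing the data, 762 genes were higher and 1563 lower, and 551 of the former and 1241 of the latter had been called without it. Whether this trend is technical or follows from the cell types that differ was not tested, so a call lost with the correction does not show that the difference is absent.

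**Figure D4:**
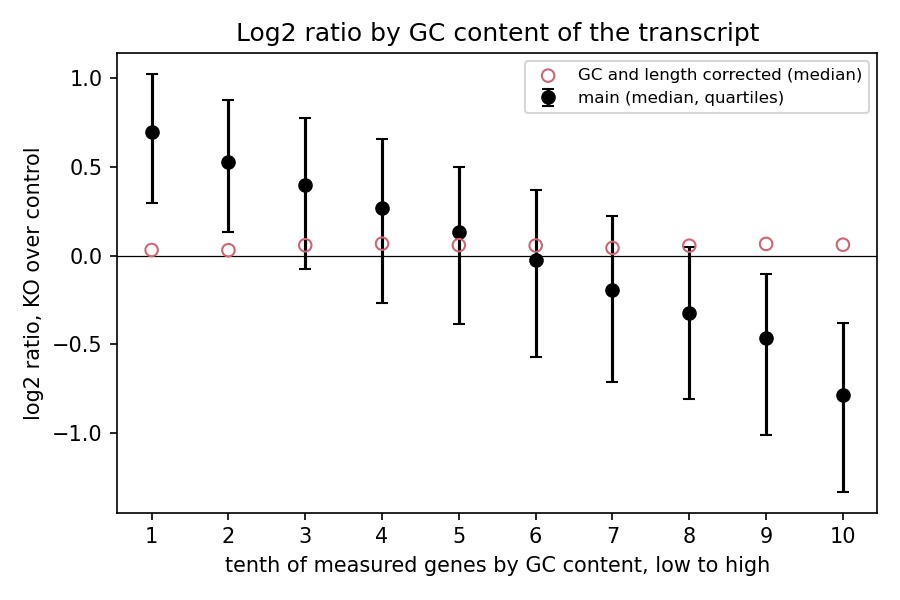
Log2 ratio of the myoFoxf1 KO over the control library in 10 equal groups of the measured genes ordered by GC content of the longest transcript; black points are medians with quartiles and red circles are medians after the GC and length correction. The uncorrected medians went from 0.70 in the lowest group to -0.79 in the highest.

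The 12 genes with the highest ratios among those of at least 10 CPM were mostly genes of skeletal muscle and peripheral nerve. Myh4, a fast muscle myosin on chromosome 11 from 67238029 to 67260446, had 1 read in the control and 322 in the knockout (8.09, 95% interval 6.25 to 14.05), and Myh1, a neighbouring myosin that can share its reads, had 2 and 270. Ckm (5.70), Atp2a1 (4.89), Mylpf (4.74) and Acta1 (4.09) are also muscle genes. The neurofilament genes Nefl (6.40) and Nefm (3.86) and the synuclein gene Sncg (3.70) are genes of nerve. Rag1, a recombinase of developing lymphocytes, had 7 and 334 reads (5.88), and Cpa3, a mast cell protease, 23 and 177 (3.32).

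The 12 lowest ratios began with Ang5, with 304 reads in the control and none in the knockout, at least 76.3-fold lower when 3 reads are taken as the limit of the knockout library. Ang5 belongs to a family of near-identical genes, so its reads may have been assigned to relatives. Psca (-6.07), Lypd2 (-3.22), Cldn7 (-2.85), Cyp2a5 (-2.75) and the cilium gene Tekt4 (-3.27) followed, with the antibody gene Ighg1 (-4.35), the chaperone gene Hspb1 and the growth factor binding protein gene Igfbp6 (-3.14). Itpka (-2.86), Nkain4 (-2.78) and Plac9a (-2.75) completed the 12, and Plac9a can share reads with its copy Plac9b.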

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

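The GC and length correction, the scaling to the fibroblast markers and the tests with them were chosen after seeing the data, and the other alternatives before. Lists that gained or lost standing or turned sign under an alternative are given in the report beside most of them, and the correction could also remove differences that belong to the cells, such as that of Foxf1, at -0.86. The count of genes called higher, 1355 without alternatives, was 587 with total reads alone and 907 with a minimum of 10 CPM. With FPKM plus 1 and plus 0.1 it was 313 and 502, and 762 with the GC and length correction. It was 3193 and 174 under the 1.5-fold and 4-fold rules, and 714 when the interval had to exclude 2-fold. The count called lower, 2053, was 3212 with total reads alone, 911 with a minimum of 10 CPM, 3390 and 397 under the 1.5-fold and 4-fold rules, and 932 when the interval had to exclude 2-fold. Stricter rules give fewer calls by construction, scaling by total reads alone shifts each ratio down, and other causes were not tested. Foxf1 kept its direction and its call except at -0.86 with the correction and -0.33 relative to the fibroblast markers. Cdh2 lost its call at 0.73 with total reads alone, 0.092 and 0.43 with FPKM plus 1 and plus 0.1, 0.91 with the correction and 0.95 with a prior count of 2, and its 36 reads in all limit any statement on it. Cdh11 was called under none of these alternatives and was at 0.50 relative to the fibroblast markers. That scaling raises every ratio alike, so Cdh2 kept its call there by construction. The lists of fibroblast, macrophage, epithelial, collagen and interferon genes stood apart in the same direction under all alternatives run on lists. Among 170 other named genes, 37 lost the call with the correction, 9 with total reads alone, 35 and 20 with FPKM plus 1 and plus 0.1, and none with median-of-ratios factors or a prior count of 2. None of the named genes that were called changed sign under the alternatives run on them.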

Other observations

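The tests of a common factor, of neutrophil markers, of collagen genes against fibroblast markers and of mixed sexes, the lists of ciliated, plasma, macrophage, muscle, nerve, thymocyte, mast and Schwann cell genes, and the GC and length correction were chosen only after the data were seen. Genes of ciliated cells were lower in the knockout library, with a median log2 ratio of -1.53 (percentile 0) and 12 of 15 called, Tekt1 at -2.15 and Rsph1 at -2.02 among them. Plasma cell and immunoglobulin genes had a median of -0.95 (percentile 0.02), or -0.63 with the correction, and 6 of 12 were lower. Ighm fell from 497 to 204 CPM and Igkc from 575 to 243 CPM, and reads of immunoglobulin genes can be shared between copies.

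Genes of monocytes and monocyte-derived macrophages had a median of 0.69 (percentile 99.6), with 5 of 18 higher, Gpnmb from 263 to 874 CPM (1.73), Ms4a7 (1.70) and F13a1 (1.51) among them. Genes of resident alveolar macrophages had a median of 0.35 (percentile 45.7), or 0.49 (percentile 93.0) with the correction, and 3 of 15 were higher, Siglec1 (1.35), Atp6v0d2 (1.34) and Ctsk (1.29). The difference between these lists was not tested. Thymocyte genes had a median of 0.45 (percentile 97.0), with Dntt (3.62) and Themis (2.17) higher, and of 0.26 with the correction. Cardiac muscle genes had a median of -0.82 (percentile 14.1), or -0.49 corrected, with Tnni3 lower (-2.80) and Tnnt2 higher (1.66, on 11 and 27 reads). The Schwann cell and mast cell lists had 4 and 2 measured genes, too few to score, with medians of -0.23 and 0.68.

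Fibroblast markers, collagen genes and Foxf1 were lower together in the knockout library. GC content and length alone do not account for this in the lists, since the 37 fibroblast markers and collagen genes together had a corrected median of -0.83, below the central 95% of random lists, although Foxf1 itself went from -1.27 (-1.77 to -0.81) to -0.86 (-1.36 to -0.40) and lost its call because the corrected ratio lies under 2-fold. Neutrophil markers lay above those of fibroblasts, endothelial, epithelial, mesothelial and smooth muscle cells and pericytes. The medians differed by 1.96 (bootstrap 95% interval 1.41 to 3.10), or 1.69 (1.43 to 2.82) with the correction. These values argue against a smaller share of all non-macrophage cells by 1 factor, if the markers stand for neutrophils alone. The list medians were known before this comparison was chosen, so it is not an independent test. Among the 6 types without neutrophils, the pericyte (-0.05) and smooth muscle (-0.38) medians did not stand apart, and the other medians stood apart lower. Whether 1 factor may account for the values of all 6 types stays open. Their list medians spanned 1.62 against a limit of 1.45 from resampled lists, but 1.28 against 1.44 with the correction. So 1 factor cannot be told apart from different factors. Bootstrap intervals in this paragraph resample genes, which are not replicates. Collagen genes that are not fibroblast markers were less lowered than the markers, with medians that differed by 0.32 (-0.51 to 0.72), or 0.17 (-0.48 to 0.94) with the correction, so a further fall of collagen genes was not seen and the intervals leave either sign open. The genotype is confounded with the make-up of the 2 preparations, and an effect of Foxf1 loss within fibroblasts remains untested.

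Skeletal muscle and nerve transcripts were high in the knockout library. Reads shared between similar genes do not account for all muscle genes, since 11 single-copy muscle genes had a median of 2.44, of which 6 were called higher, Pvalb at 0 and 77 reads, Neb at 8 and 73 and Ttn at 30 and 124 among them. A candidate explanation is a piece of tissue other than lung in the knockout preparation: muscle and neuron genes not used to notice the pattern had medians of 2.69 and 1.77, with 12 of 19 and 9 of 12 called higher and Nefh at 1.89 and 17.1 CPM, but the neuron median missed the 2 set beforehand, which keeps this open. These medians rest on genes with few control reads. The 10 muscle genes of at least 1 CPM in the control had a median of -0.029 with 3 higher. The 6 single-copy ones had -0.28 with Ttn alone higher. The 7 such neuron genes had 1.01 with 4 higher and Calca, the most abundant, at -0.60. Genes under 1 CPM in the control were measured only through the knockout library, which raises the full medians. A minimum in the control in turn leaves out genes nearly absent from it, which other tissue would add. So neither set of medians decides the question. No gene of either list was in a list fixed earlier, and Pygm (-0.50), Ryr1 (-0.07), Cacna1s (-0.67), Ampd1 (-0.01) and Trim72 (-0.90), single-copy genes also read in the control, were not called.

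Y-linked transcripts and Xist, which is made from the inactive X chromosome of females, were present in both libraries at different levels, and their list had a median of 2.00 (percentile 100) with 4 of 5 higher, and of 1.39 with the correction. Ddx3y had 558 reads in the control and 2006 in the knockout (2.25, corrected 1.49), Uty 121 and 432 (2.24, corrected 1.43), Kdm5d 62 and 188 (2.00, corrected 1.39) and Eif2s3y 364 and 890 (1.70, corrected 1.02), while Xist had 2611 and 1155 (-0.77, not called, and -1.47 and called with the correction). Reads of the X-linked homologs do not account for this, since the 4 ratios of a Y-linked gene to its homolog changed by a median of 1.68. Xist and all 4 Y-linked genes were read in both libraries, the lowest count being 62 reads. This argues against RNA of 1 sex alone in either library. Whether male and female mice were pooled stays open, since these counts prompted the idea and are not an independent test of it. The sex and number of the animals are not given in the sources used here. A difference between the groups in the shares of male and female RNA stays among the open explanations of other differences.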
